A study of Rattus norvegicus with 24 samples.

How the data were processed

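The series holds RNA immunoprecipitation sequencing (RIP-seq) of primary rat dorsal root ganglion neurons. Per the labels, the ganglia came from Sprague-Dawley rat embryos at embryonic day 15, and the neurons were kept for 5 days with nerve growth factor and brain-derived neurotrophic factor, with the antimitotic cytosine arabinoside. Lysates were incubated with protein A/G beads carrying 5 µg of an antibody to SFPQ, an antibody to SRSF10 or rabbit IgG, a control antibody that recognises neither protein. Bound RNA was released with proteinase K and purified with phenol and chloroform, per the labels' protocols. RNA of immunoprecipitates (IP) and of input was sequenced, and the labels do not say which IP and input share a lysate. Deviations from the group mean correlated over 0.1 between IP and input of the same number in all 4 IgG pairs (0.2, 0.58, 0.45 and 0.53). By the rule set beforehand the numbers were therefore taken to pair the IgG IP with its input, which the labels do not state. IgG IP replicates 1 and 3 correlated about as highly with an input of another number (0.17 and 0.45), so this pairing is uncertain. There were 24 libraries, in 6 groups of 4: IP and input for each of the 3 antibodies. The labels call the replicates biological but do not say that each came from a separate culture or litter, so p-values measure the spread between these samples, part of which can be technical.

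The deposited values are raw read counts per gene, and the authors made them as follows as far as the sources tell. Libraries were made with the SMART-Seq v4 kit, per the labels' protocols: cDNA is primed with oligo-dT and extended by template switching, so RNAs without a poly(A) tail are taken up poorly, and the kit does not mark strand. No molecular identifiers are named, so reads are not independent molecules, and the counts can include PCR copies. Reads were demultiplexed with bcl2fastq 2.18 and aligned with STAR to the rat build rn6, per the submitters' processing notes. The version of STAR, the counting tool, its strand setting and the annotation release are not given in the sources used here. Without a stated strand setting, reads of overlapping genes cannot be told apart. The values are whole numbers, and their column totals run from 10.6 to 21.4 M.

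The table holds 32011 genes by symbol. Of these names, 20869 are current symbols in a RefSeq gene table of assembly GRCr8 and 2151 are older symbols there. That table was used only for names and for which genes neighbour each other, since the counts were made on another build. Of 145 genes named by the rule below, 142 were found in it, 54 overlap another gene there and 27 overlap one with a symbol. No replicate pair within a group agreed within sampling noise by a chi-square test over genes with at least 20 counts, so all 24 libraries were counted as separate samples.

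Differential abundance was tested from the counts as deposited with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr with its default minimum of 10 counts (16294 genes kept, 99.8 to 99.97% of the counts), glmQLFit on all 24 libraries with 1 coefficient per group and no covariate, and the two-sided glmQLFTest. Adjusted p is by Benjamini-Hochberg with a threshold of 0.05. The comparisons were IP against input for SFPQ, SRSF10 and IgG; the enrichment of SFPQ and of SRSF10 beyond IgG, which is the difference between the IP to input ratio of that antibody and that of IgG; the enrichment of SFPQ against that of SRSF10; and the 3 groups of inputs against each other. The standard error (SE) is the log2 fold change divided by the square root of the F statistic. CPM are counts per M on TMM-scaled library sizes. Shares of counts were compared between groups with two-sided exact permutation tests, whose smallest possible p with 4 against 4 libraries is 0.0286.

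Before the data were examined, 22 gene lists were fixed: long neuronal genes; nuclear and imprinted long noncoding RNAs; paraspeckle and DBHS-partner proteins (DBHS is the family of SFPQ); SR splicing factors; hnRNP proteins; cytosolic ribosomal proteins; nuclear-encoded oxidative phosphorylation; mitochondrially encoded genes; translation elongation and TOP mRNAs; replication-dependent histones; axonal cytoskeleton; motors and axonal transport; Bcl2 family and lamins; sensory neuron identity; voltage-gated channels; synapse and vesicle release; Schwann and satellite glia; fibroblast and meninges; endothelium and blood; proliferation; immediate early and stress; and secretory and extracellular matrix. Of the 17 long noncoding RNAs written in their list only 7 were measured, so its results cover only part of it. Lists with at least 3 measured members were tested with camera (limma 3.58.1) with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. The same lists were tested with a correlation estimated per list and with fry, which asks whether a list moves one way on balance and compares it with no other genes.

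The genes named were chosen by a rule fixed before the data were examined. In each comparison they are the 8 largest upward and 6 largest downward log2 fold changes past the threshold, among genes with a mean of at least 10 CPM whose libraries in the IP all lie on one side of those in the input (for the enrichments, of those in the other IP), identifiers without a symbol left out. To these come up to 3 members with the smallest p of each list described, and 9 genes fixed by name: Sfpq, Srsf10, Bcl2l2, Lmnb2, Neat1, Malat1, Bclaf1, Lpin1 and Nasp. Of the 9, 7 have counts in the table; Neat1 and Malat1 were not analysed here.

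The alternatives fixed beforehand were DESeq2 1.42.0 with its size factors, limma voom with quality weights, scaling by library size only, no filter, a filter at a mean of 10 CPM, a log2 fold change of at least 1, a fit on the groups compared alone, IP against the other IP without inputs, a block for the replicate number in 2 forms, and leaving out each library in turn. A fit without the 4 libraries with over 4% of counts in mitochondrial rRNA was added after the data were seen.

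The tests were tried on simulated counts with the means, library sizes and spread of the real genes, over 16294 genes. Of genes changed 4-fold, edgeR recovered 53% in SFPQ IP against input, 65.2% in SRSF10 IP against input, 62.1% in IgG IP against input, 30.3% in SFPQ enrichment beyond IgG, 28.8% in SRSF10 enrichment beyond IgG and 45.5% in SFPQ against SRSF10 enrichment. Of genes changed 2-fold, it recovered 6%, 11.9%, 14.9%, 3%, 0% and 3% in the same order. Between 0 and 2 unchanged genes were called. The simulation drew genes independently and gave all groups the same spread per gene. In the real data the biological coefficient of variation ran from 0.259 in the IgG input to 0.553 in the SRSF10 input. The few unchanged genes called therefore do not measure false calls in the real data. Transcript lengths of the build were not used here, so a dependence on length was not examined.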

Results

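RNA bound to the RNA-binding proteins SFPQ and SRSF10 was compared with input RNA in cultured sensory neurons from the dorsal root ganglia of rat embryos. SFPQ belongs to the DBHS family of nuclear RNA-binding proteins and also carries mRNAs in axons. SRSF10 is a serine- and arginine-rich splicing factor. A non-immune rabbit IgG served as the control antibody. Each of the 3 antibodies had 4 IP libraries and 4 input libraries, 24 in all. Total counts averaged 21.1 ± 0.485 M (SD, n = 4) in the SFPQ IP, 14.6 ± 4.13 M in the SRSF10 IP and 17.2 ± 1.61 M in the IgG IP. The inputs averaged 17.5 ± 1.23, 15.3 ± 2.85 and 19.5 ± 1.36 M for SFPQ, SRSF10 and IgG. The shallowest library was SRSF10 IP replicate 3, with 10.6 M counts.

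Mitochondrial rRNA made up very different parts of the libraries. In the SFPQ IP it held 0.0271 ± 0.0117% of counts (SD, n = 4), against 3.01 ± 1.92% in the SFPQ input. The SRSF10 IP held 3.74 ± 3.60% and its input 4.33 ± 2.37%, and the IgG IP held 1.18 ± 1.14% and its input 2.79 ± 0.570%. The SFPQ IP libraries all lay below the SFPQ input and below the IgG IP, each at exact permutation p = 0.0286, adjusted p = 0.0572 over 6 comparisons, which misses the threshold. The mRNAs of cytosolic ribosomal proteins held 0.380 ± 0.165% of counts in the SFPQ IP against 1.90 ± 0.688% in its input (exact permutation p = 0.0286, adjusted p = 0.0858). In the IgG IP they held 0.986 ± 0.522% (exact permutation p = 0.0857 against the SFPQ IP, adjusted p = 0.129). In 4 libraries mitochondrial rRNA held over 4% of counts: 5.87% in SFPQ input replicate 4, 8.96% in SRSF10 IP replicate 3, 7.33% in SRSF10 input replicate 3 and 4.99% in SRSF10 input replicate 4.

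**Figure D1:**
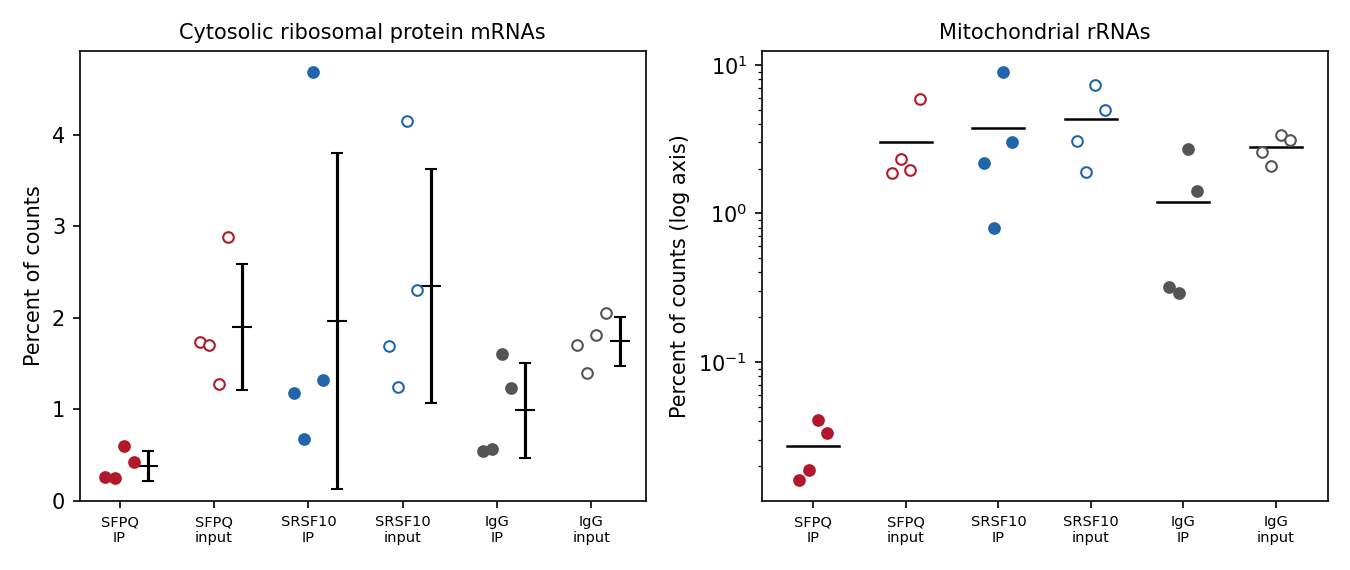
Percent of counts in mRNAs of cytosolic ribosomal proteins (left, linear axis) and in mitochondrial rRNAs (right, log axis) in each of the 24 libraries, a point each (filled for IP, open for input), with the mean ± SD beside them on the left and the mean as a line on the right. The SFPQ IP lies lowest in mitochondrial rRNA, at a mean of 0.0271%, and SRSF10 IP replicate 3 highest in both, at 4.69% and 8.96%.

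The first comparison asked which RNAs held a larger or smaller share in the SFPQ IP than in its input. Higher in the SFPQ IP were 18 of 35 long neuronal genes, 16 of 31 genes of motors and axonal transport (3 lower) and 22 of 40 voltage-gated channels. Lower were 71 of 75 ribosomal protein genes, 63 of 73 genes of oxidative phosphorylation and both mitochondrial rRNAs. Each of these 5 lists passed as a list, and none did with an estimated correlation (adjusted p = 0.456 with an estimated correlation for each). Counts adjusted over the list alone are given below. With fry each of the 5 passed (adjusted p from 0.000332 to 0.00299), as did the secretory, TOP and histone lists described below (0.00175 to 0.00606). Kif5b, a kinesin heavy chain, stood at 405 ± 89.9 CPM (SD, n = 4) in the SFPQ IP and 158 ± 14.4 CPM in the input, a log2 fold change of 1.36 (SE 0.19, adjusted p = 8.65e-05). Nrxn1, a presynaptic adhesion protein, stood at 826 ± 116 and 328 ± 66.0 CPM (log2 1.33, SE 0.20, adjusted p = 0.000111). Scn9a, the sodium channel of pain-sensing neurons, stood at 484 ± 101 and 194 ± 31.8 CPM (log2 1.32, SE 0.20, adjusted p = 0.000122). In the IgG IP the same 3 genes had log2 fold changes over input of 0.36, 0.26 and 0.44, none of which passed the threshold.

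The largest increases in the SFPQ IP that met the naming rule were in Zbtb20, a transcriptional repressor (log2 2.42, SE 0.46), Csrnp3 (2.17, SE 0.34), Dennd1b, which activates Rab GTPases (2.12, SE 0.43), and Cpd, a carboxypeptidase of the secretory pathway (2.11, SE 0.41). Clcn5, a chloride and proton exchanger, rose by 2.10 (SE 0.54), followed by Slco5a1 (2.01, SE 0.54), Dpy19l4 (1.98, SE 0.38) and Xkr4 (1.97, SE 0.46). These had adjusted p from 0.000153 to 0.00618. Of 35 long neuronal genes, 18 rose and 1 fell (20 and 1 adjusted over the list alone). The median log2 was 0.95 (adjusted p = 0.000156, and adjusted p = 0.456 with an estimated correlation). Lsamp, a neural adhesion protein, rose by 1.39 and Ptprd by 1.46. Of 40 voltage-gated channels, 22 rose and 1 fell (28 and 1 adjusted over the list alone), among them Cacna2d1 at 1.74 and Kcna1 at 1.55. The median of the list was 0.98 (adjusted p = 6.21e-06, and adjusted p = 0.456 with an estimated correlation). Of 31 genes of motors and axonal transport, 16 rose and 3 fell (18 and 3 adjusted over the list alone), with Kif5c at 1.56 and the dynein adaptor Bicd1 at 1.5. As a list they had a median of 0.92 (adjusted p = 0.00113, and adjusted p = 0.456 with an estimated correlation). Of 30 secretory and extracellular matrix genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone), with Lamc1, a laminin chain, at 1.40, the endoplasmic reticulum chaperone Hsp90b1 at 1.08 and Pdia3 at 0.88. Their median was 0.85 (adjusted p = 0.0102, and adjusted p = 0.456 with an estimated correlation). The secretory call was lost with a filter at 10 CPM (adjusted p = 0.0608).

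Among genes that met the naming rule, the mitochondrial rRNAs, Rn7sl1 and several short abundant mRNAs fell furthest in the SFPQ IP. mt-Rnr2, the large mitochondrial rRNA, stood at 223 ± 110 CPM in the SFPQ IP and 31100 ± 22700 CPM in the input (SD, n = 4; log2 -7.13, SE 0.93, adjusted p = 4.61e-05). mt-Rnr1, the small one, had a log2 of -5.51 (SE 0.93). These are the 2 genes measured whose names begin with mt-, which defines the list of mitochondrially encoded genes. Mitochondrial genes under other names would not be counted in it. Both fell over all genes and adjusted over the list alone. Uqcr10, a subunit of respiratory complex III, fell by 5.22, Tmsb10, an actin-binding thymosin, by 5.08 and Atp5e, a subunit of ATP synthase, by 5.05, at adjusted p from 0.000163 to 0.00045. Rn7sl1, the RNA of the signal recognition particle, had 0, 3, 0 and 2 counts in the 4 SFPQ IP libraries against 20.1 ± 17.4 CPM in the input (adjusted p = 0.000723). Its reads can come from near-identical copies. Of 75 ribosomal protein genes, 71 fell (72 adjusted over the list alone), with Rpl35 at -4.04, Rps26 at -4.26 and Rpl10 at -2.96. The median of the list was -3.00 (adjusted p = 8.95e-26, and adjusted p = 0.456 with an estimated correlation). Of 73 nuclear-encoded genes of oxidative phosphorylation, 63 fell and 2 rose (64 and 3 adjusted over the list alone), with Cox8a at -4.15, Ndufc1 at -4.12 and Cox4i1 at -2.96. As a list they had a median of -2.82 (adjusted p = 4.85e-21, and adjusted p = 0.456 with an estimated correlation). Of 25 translation elongation and TOP mRNAs, 15 fell and 3 rose (15 and 3 adjusted over the list alone), with Uba52 at -3.86, Ybx1 at -2.96 and Npm1 at -1.90. Their median was -1.28 (adjusted p = 0.000156, and adjusted p = 0.456 with an estimated correlation). Of 21 histone genes, 10 fell (10 adjusted over the list alone), with Hist3h2ba at -3.21, Hist3h2a at -1.89 and H1fx at -1.34. The list was matched by name and takes in linker histones such as H1fx and H1f0, so not every member need be replication-dependent. In the inputs 7 of its genes had a mean under 1 CPM. The median of the list was -1.76 (adjusted p = 0.000384, and adjusted p = 0.456 with an estimated correlation). Reads of Ybx1 and of histones can be shared with near-identical genes, and Rpl35, Cox8a, Uqcr10, Rps26, Pdia3, Ptprd and Bicd1 overlap another gene with a symbol, so their values are uncertain. Kif5b, Nrxn1, Zbtb20, Csrnp3, Lsamp, Kif5c, Cacna2d1, Dennd1b, Xkr4 and Npm1 overlap genes without a symbol.

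In total, 2869 of 16294 genes were higher and 3132 lower in the SFPQ IP than in its input (edgeR, adjusted p under 0.05). Sfpq itself stood at 57.3 ± 8.61 CPM in the IP and 59.9 ± 12 CPM in the input (log2 -0.06, SE 0.19, adjusted p = 0.821; 0.11 with scaling by library size only). Bcl2l2 and Lmnb2, mRNAs of a survival protein and a nuclear lamin, had log2 values of -0.29 (adjusted p = 0.364) and 0.66 (adjusted p = 0.0994). Lpin1 at 0.85, Bclaf1 at 0.42, Nasp at -0.75 and Srsf10 at -0.06 (0.13 with library size only) did not pass the threshold either. Scaling by library size only moved the median of all genes from 0.09 to 0.26, so changes are relative to that shift. limma voom with quality weights called 4473 genes higher, and 1884 of the genes higher had a log2 of at least 1.

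**Figure D2:**
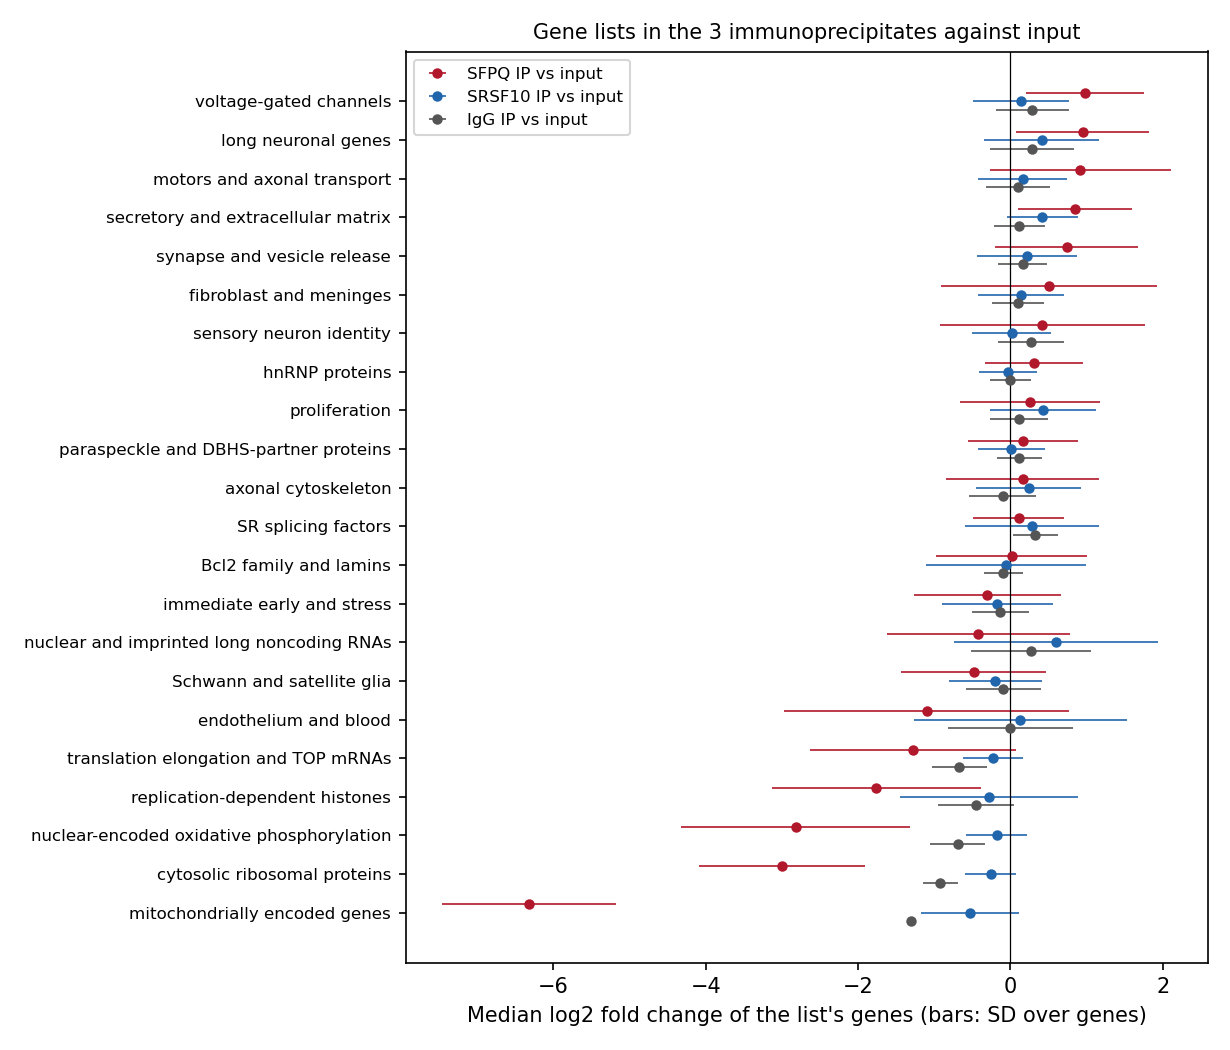
Median log2 fold change of IP over input (horizontal axis, log2) for the genes of each of the 22 lists (vertical axis) with the SFPQ, SRSF10 and IgG antibodies, with bars for the SD over the genes of a list. In the SFPQ IP the medians run from -6.32 for the 2 mitochondrially encoded genes to 0.98 for voltage-gated channels.

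The same question was asked of SRSF10. Srrm2, Pnisr and Luc7l3, which encode proteins of splicing, were higher in the SRSF10 IP. Srrm2, a scaffold protein of nuclear speckles, stood at 609 ± 257 CPM in the IP and 88.9 ± 4.73 CPM in the input (SD, n = 4; log2 2.78, SE 0.28, adjusted p = 5.68e-06). Pnisr, a serine- and arginine-rich nuclear protein, stood at 282 ± 66.3 and 67.4 ± 25.8 CPM (log2 2.06, SE 0.29, adjusted p = 0.000141). Luc7l3, a splicing factor, stood at 288 ± 119 and 71.7 ± 16.0 CPM (log2 2.01, SE 0.30, adjusted p = 0.000232). Of 28 SR splicing factors, 9 rose and 1 fell (11 and 1 adjusted over the list alone). Their median log2 was 0.29 (adjusted p = 0.000165, and adjusted p = 0.526 with an estimated correlation and 0.00074 with fry). The same list had a median of 0.33 in the IgG IP (adjusted p = 0.000114, and adjusted p = 0.335 with an estimated correlation). With SRSF10 beyond IgG it did not pass (median 0.18, adjusted p = 0.224), with 2 genes higher and 1 lower (5 and 1 adjusted over the list alone).

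Among the largest increases in the SRSF10 IP were also Ahnak2, a very large scaffold protein (log2 3.64, SE 0.36), Stard9, a kinesin (3.12, SE 0.41), and Filip1l (2.80, SE 0.54). Also higher were Foxh1, a transcription factor (2.69, SE 0.32), Timm50, an import receptor of mitochondria (2.66, SE 0.31), Pclo, a scaffold of the presynaptic active zone (2.63, SE 0.40), and Hist1h1d, a linker histone (2.56, SE 0.51). All 7 had adjusted p from 5.68e-06 to 0.00311. The value of Hist1h1d was 1.38 without SRSF10 IP replicate 3, still past the threshold. That library stood at 204.4 CPM, with the nearest IP library at 44.71 CPM. The largest decreases were smaller: Ccni, a cyclin (-1.42, SE 0.24), Gabra5, a GABA receptor subunit (-1.40, SE 0.34), Rab5c, an endosomal GTPase (-1.30, SE 0.29), Zfp575 (-1.27, SE 0.29), Cdkn1b, an inhibitor of the cell cycle (-1.27, SE 0.32), and Pdzd4 (-1.26, SE 0.32). Their adjusted p ran from 0.000765 to 0.0163. In a fit on the 8 SRSF10 libraries alone the calls of these 6 genes, of Filip1l, Hist1h1d and Luc7l3 ended, and Cdkn1b, Pdzd4 and Gabra5 also lost theirs without 1 library (adjusted p of up to 0.0707, 0.0597 and 0.0852). Gabra5 and Zfp575 also lost it without the 4 libraries with over 4% mitochondrial rRNA, and Gabra5 with limma voom. Bcl2l2 was lower, at 28.5 ± 7.59 CPM against 51.9 ± 16.5 CPM (log2 -0.86, SE 0.24, adjusted p = 0.0279). This call was lost with library size only (adjusted p = 0.122), no filter (0.0516) and the 8 SRSF10 libraries alone (0.245). It was also lost without SRSF10 input replicate 1 (0.096), SRSF10 input replicate 4 (0.0736), SRSF10 IP replicate 2 (0.0558) or SRSF10 IP replicate 4 (0.0982). Srsf10 itself had a log2 of -0.35 (adjusted p = 0.326), Sfpq -0.04 (0.937; 0.02 with library size only), Lpin1 0.60 (0.384), Nasp 0.58 (0.329), Bclaf1 0.43 (0.163) and Lmnb2 0.24 (0.729). Timm50 was also abundant in the IgG IP, at 518 ± 290 CPM against 620 ± 154 CPM in the SRSF10 IP. Stard9, Filip1l, Foxh1 and Ccni overlap another gene with a symbol, and linker histones share reads, so their values are uncertain. Srrm2 and Lmnb2 overlap a gene without a symbol.

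Of 75 ribosomal protein mRNAs edgeR called 0 in the SRSF10 IP, and 0 at unadjusted p under 0.05 (0 by DESeq2, 1 lower by limma voom, 0 adjusted over the list alone). Their median was -0.26 (adjusted p = 0.000351, and adjusted p = 0.81 with an estimated correlation and 0.712 with fry). Their median was 0.43, 0.03 and 0.08 without SRSF10 input replicate 3, SRSF10 IP replicate 1 or SRSF10 IP replicate 2, and DESeq2 lost the call (adjusted p = 0.103), as did a filter at 10 CPM (0.0524). Without SRSF10 IP replicate 3 it was -1.62 (adjusted p = 3.32e-19). Of the 73 nuclear-encoded genes of oxidative phosphorylation edgeR called 0 (5 higher and 1 lower at unadjusted p under 0.05; 3 higher by DESeq2, 2 higher and 6 lower by limma voom; 0 adjusted over the list alone). That list had a median of -0.18 (adjusted p = 0.00922, and adjusted p = 0.81 with an estimated correlation and 0.712 with fry). That median was 0.45, 0.06, 0.04 and 0.05 without SRSF10 input replicate 3 or SRSF10 IP replicates 1, 2 or 4, and the call was lost by DESeq2 (adjusted p = 0.331) and at 10 CPM (0.149). Without SRSF10 IP replicate 3 it was -1.56 (adjusted p = 1.18e-14). Of 25 translation elongation and TOP mRNAs 1, Ybx1, fell (0 adjusted over the list alone). Ybx1 lost the call in 5 of the 8 fits without 1 library (adjusted p of up to 0.161 without SRSF10 input replicate 4), at 10 CPM, with no filter, in the 8 SRSF10 libraries alone and without the 4 libraries with over 4% mitochondrial rRNA. The list had a median of -0.23 (adjusted p = 0.0337, and adjusted p = 0.81 with an estimated correlation and 0.618 with fry). This call was lost by DESeq2 (adjusted p = 0.103), at 10 CPM (0.149), and without SRSF10 input replicate 3 (0.49) or SRSF10 IP replicates 1, 2 or 4 (0.145, 0.18 and 0.0617). Replicate 3 of the IP and of the input had the highest shares of ribosomal protein mRNA of their groups, 4.69% and 4.15%.

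In total, edgeR called 977 genes higher and 388 lower in the SRSF10 IP than in its input. These counts were 1672 and 1363 without SRSF10 IP replicate 3, and 433 and 104 without IP replicate 4. They were 678 and 189 without IP replicate 2, 591 and 202 without input replicate 1, and 548 and 164 without input replicate 4. A fit on the 8 SRSF10 libraries alone called 31 higher and 0 lower by edgeR, with 729 lower at unadjusted p under 0.05. On all 24 libraries DESeq2 called 589 lower, limma voom 1543 higher and 779 lower. Scaling by library size only gave 211 lower, a fit with no filter 193, and 94 of the genes lower had a log2 of at least 1 in size.

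The IgG IP measured what beads and a control antibody held back. Timm50 stood at 518 ± 290 CPM in the IgG IP and 87.0 ± 4.21 CPM in its input (SD, n = 4; log2 2.57, SE 0.31, adjusted p = 0.000189). Dusp23, a phosphatase, stood at 62.5 ± 25.2 and 13.0 ± 1.29 CPM (log2 2.26, SE 0.24, adjusted p = 3.51e-05). Dnajb4, a heat shock cochaperone, stood at 414 ± 170 and 92.4 ± 6.83 CPM (log2 2.16, SE 0.28, adjusted p = 0.000358). Slc25a16, a mitochondrial carrier, stood at 337 ± 110 and 91.8 ± 11.9 CPM (log2 1.88, SE 0.30, adjusted p = 0.00469). These 4 genes passed the threshold in all 8 fits that left out 1 library of the comparison. Exoc2 of the exocyst (1.67), the growth factor homologue Fgf12 (1.61), Gca (1.61) and Eogt (1.58) rose too. They lost the call in 2 to 7 of the 8 fits, at adjusted p of up to 0.0739, 0.052, 0.209 and 0.224 without IgG input replicate 4 or, for Fgf12, IgG IP replicate 4. In the 8 IgG libraries alone Exoc2, Fgf12 and Gca lost it, and with library size only Eogt and Gca. Slc25a16, Exoc2 and Gca overlap another gene with a symbol, and Fgf12 and Nrg1 genes without one.

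In the IgG IP, none of the lists named here passed with fry (adjusted p from 0.0824 to 0.496). By gene list, cytosolic ribosomal protein mRNAs had a median log2 of -0.92 in the IgG IP (adjusted p = 1.74e-22, and adjusted p = 0.455 with an estimated correlation). By edgeR 0 of 75 passed (7 lower at unadjusted p under 0.05; 0 by DESeq2, 5 lower by limma voom; 0 adjusted over the list alone). Oxidative phosphorylation genes had a median of -0.69 (adjusted p = 1.38e-12, and adjusted p = 0.471 with an estimated correlation). edgeR called 0 of 73 genes (4 lower at unadjusted p under 0.05; 0 by DESeq2, 3 lower by limma voom; 0 adjusted over the list alone). Translation elongation and TOP mRNAs had a median of -0.67 (adjusted p = 2.89e-09, and adjusted p = 0.338 with an estimated correlation). Of its 25 genes edgeR called 0 (6 lower at unadjusted p under 0.05; 1 by DESeq2, 4 by limma voom; 2 lower adjusted over the list alone). Histones had a median of -0.45 (adjusted p = 0.00584, and adjusted p = 0.471 with an estimated correlation). Past the threshold by edgeR were 0 of 21 (1 lower at unadjusted p under 0.05; 0 by DESeq2, 2 by limma voom; 0 adjusted over the list alone). On the higher side, 1 of 35 long neuronal genes, Nrg1, rose (2 adjusted over the list alone). The list had a median of 0.28 (adjusted p = 0.000931, and adjusted p = 0.338 with an estimated correlation). Of 40 voltage-gated channels 1 rose, Scn2a (4 adjusted over the list alone), and the median was 0.29 (adjusted p = 0.0363, and adjusted p = 0.743 with an estimated correlation). Nrg1 and Scn2a each lost the call in 7 of the 8 fits, with library size only, with no filter and in the 8 IgG libraries alone. With a replicate block of antibody and number Scn2a (1.06) also missed the threshold. The channels as a list lost theirs with limma voom (adjusted p = 0.084), with no filter (0.0919) and without IgG input replicates 3 or 4 (0.104 and 0.134) or IgG IP replicate 1 (0.443). SR splicing factors had a median of 0.33 (adjusted p = 0.000114, and adjusted p = 0.335 with an estimated correlation). By edgeR 0 of 28 passed (5 higher at unadjusted p under 0.05; 0 by DESeq2, 4 by limma voom; 3 adjusted over the list alone). The 7 nuclear and imprinted long noncoding RNAs had a median of 0.27 (adjusted p = 0.00215, and adjusted p = 0.335 with an estimated correlation). edgeR called 0 of them (3 higher at unadjusted p under 0.05; 2 by DESeq2, 2 by limma voom; 2 adjusted over the list alone). Among them the RNA named RGD1566401, an older name of the imprinted Meg3, stood at 960 ± 391 CPM against 226 ± 69.8 CPM in the input (adjusted p = 0.117, and 0.0305 with a replicate block of antibody and number). Snhg11 of the same list also passed the threshold with that block.

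In total, edgeR called 32 genes higher and 0 lower in the IgG IP than in its input, with 926 higher and 359 lower at unadjusted p under 0.05. This fit holds no block for the pairing by number, and a fit with such a block called more genes higher, as given further below. DESeq2 called 147 higher and 8 lower and limma voom 504 and 211. Without IgG input replicates 1, 2, 3 or 4 it called 9, 9, 6 and 7 higher. Without IgG IP replicates 1, 2, 3 or 4 it called 13, 9, 84 and 7, with 2 lower without IP replicate 3. A filter at 10 CPM gave 62 and 2, library size only 15 higher, no filter 17 and the 8 IgG libraries alone 9. Leaving out the 4 libraries with over 4% mitochondrial rRNA, an alternative chosen after the data were seen, gave 99 and 2. The fixed genes did not pass: Srsf10 had a log2 of 0.39, Lpin1 0.32, Lmnb2 0.02, Bclaf1 -0.03 (0.04 with library size only), Sfpq -0.25, Bcl2l2 -0.45 and Nasp -0.45.

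The enrichment of SFPQ beyond IgG set the ratio of IP to input with the SFPQ antibody against that with IgG. Pde3b, a phosphodiesterase, was enriched in the SFPQ IP over the IgG IP, at 35.3 ± 3.45 CPM against 11.1 ± 2.70 CPM (SD, n = 4). Its inputs stood at 12.4 ± 3.15 and 14.3 ± 3.16 CPM (log2 difference 1.88, SE 0.36, adjusted p = 0.0133). Ptpn11, the phosphatase SHP2, had a difference of 1.65 (SE 0.34, adjusted p = 0.0176) and Scaf11, a splicing-associated SR protein, of 1.53 (SE 0.31, adjusted p = 0.0163). Foxo3, a forkhead transcription factor (2.31), Tenm3, a teneurin (1.67), the nuclear import receptor Ipo7 (1.65), Armcx4 (1.60) and Pdzd8 (1.52) were also higher. On the lower side Dusp23, enriched by IgG, stood at 4.21 ± 0.472 CPM in the SFPQ IP (difference -3.85, SE 0.34, adjusted p = 9.2e-07). mt-Rnr2 had a difference of -5.81 (SE 1.08, adjusted p = 0.0114). Lower too were Tmsb10 at -4.11, Ost4 at -3.69, Trnl1 at -3.42 and Trappc1 at -3.42. Of these 14 genes, Pde3b, Dusp23 and mt-Rnr2 passed the threshold in all 16 fits that left out 1 library. Ptpn11 and Scaf11 missed it in 1, without SFPQ IP replicate 1 (adjusted p = 0.0576 and 0.0566). The other 9 missed it in 2 to 14 fits, with adjusted p of up to 0.139. Armcx4 and Ipo7 also missed it with no filter, and Pdzd8 with library size only. Pde3b, Trappc1 and Ost4 overlap another gene with a symbol, and Tenm3 genes without one. Trnl1 was not found in the RefSeq gene table.

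Among the lists tested, the difference between SFPQ and IgG was largest for the mRNAs of ribosomal proteins and oxidative phosphorylation. With fry none of the lists called here passed (adjusted p from 0.0818 to 0.138). The 2 mitochondrially encoded genes were too few to test as a list and had a median of -5.02, with 1 lower (2 adjusted over the list alone). Ribosomal protein mRNAs had a median of -2.06 (adjusted p = 5.16e-17, and adjusted p = 0.485 with an estimated correlation). edgeR called 0 of 75 genes (47 lower at unadjusted p under 0.05; 16 by DESeq2, 68 by limma voom; 38 adjusted over the list alone). Rps12 had -3.97 (adjusted p = 0.0762) and Rpl35 -3.18 (0.0762). Oxidative phosphorylation genes had a median of -2.06 (adjusted p = 5.16e-17, and adjusted p = 0.471 with an estimated correlation). Of its 73 genes edgeR called 0 (50 lower at unadjusted p under 0.05; 27 by DESeq2, 62 by limma voom; 43 adjusted over the list alone). Uqcr10 had -4.19 (adjusted p = 0.0583). Histones had a median of -1.49 (adjusted p = 0.00527, and adjusted p = 0.536 with an estimated correlation). Past the threshold by edgeR were 0 of 21 (5 lower at unadjusted p under 0.05; 1 by DESeq2, 6 by limma voom; 1 adjusted over the list alone). The 7 long noncoding RNAs measured, of 17 in their list, had a median of -1.36 (adjusted p = 0.0314, and adjusted p = 0.471 with an estimated correlation). edgeR called 0 of the 7 (3 lower at unadjusted p under 0.05; 2 lower by DESeq2, 3 lower and 1 higher by limma voom; 3 lower adjusted over the list alone). On the higher side, voltage-gated channels had a median of 0.58 (adjusted p = 2.8e-05, and adjusted p = 0.471 with an estimated correlation). By edgeR 0 of 40 passed (8 higher and 1 lower at unadjusted p under 0.05; 3 higher by DESeq2, 11 higher and 1 lower by limma voom; 0 adjusted over the list alone). Motors and axonal transport had a median of 0.67 (adjusted p = 0.000861, and adjusted p = 0.471 with an estimated correlation). edgeR called 0 of 31 genes (13 higher and 3 lower at unadjusted p under 0.05; 4 and 1 by DESeq2, 13 and 3 by limma voom; 3 and 1 adjusted over the list alone). Kif5b had 1.00 (adjusted p = 0.0636). Long neuronal genes had a median of 0.45 (adjusted p = 0.00654, and adjusted p = 0.471 with an estimated correlation). Of its 35 genes edgeR called 0 (4 higher at unadjusted p under 0.05; 2 higher by DESeq2, 6 higher and 1 lower by limma voom; 2 adjusted over the list alone). Nrxn1 had 1.07 (adjusted p = 0.0556) and Lsamp 1.17 (0.0581). Secretory and extracellular matrix genes had a median of 0.52 (adjusted p = 0.00484, and adjusted p = 0.471 with an estimated correlation). Past the threshold by edgeR were 0 of 30 (7 higher and 1 lower at unadjusted p under 0.05; 2 higher by DESeq2, 9 higher and 1 lower by limma voom; 0 adjusted over the list alone). hnRNP proteins had a median of 0.31 (adjusted p = 0.0398, and adjusted p = 0.471 with an estimated correlation). By edgeR 0 of 23 passed (6 higher and 2 lower at unadjusted p under 0.05; 3 higher by DESeq2, 7 higher and 2 lower by limma voom; 2 adjusted over the list alone). The hnRNP call was lost at 10 CPM (adjusted p = 0.0654), with limma voom (0.0696) and in the 16 libraries alone (0.0508), and in 8 of the 16 fits without 1 library (up to 0.101 without SFPQ IP replicate 3). The long noncoding RNA call was lost at 10 CPM (0.0654), with limma voom (0.292) and without the 4 libraries with over 4% mitochondrial rRNA (0.0678), and in 3 of the 16 fits (up to 0.139 without SFPQ IP replicate 3).

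In total, edgeR called 42 genes higher and 146 lower for SFPQ beyond IgG, against 24 and 179 with scaling by library size only, which moved the median of all genes by 0.11. The fit holds no block for the replicate number, and fits with such a block called more genes in both directions, as given further below. IP against IgG IP without inputs called 941 and 1554, among them 42 of the 42 and 145 of the 146. DESeq2 called 360 and 806, limma voom 1983 and 2910, and the 16 libraries alone 523 and 1172. A filter at 10 CPM gave 183 and 261, no filter 14 higher, and the fit without the 4 libraries with over 4% mitochondrial rRNA 279 and 824. Without SFPQ IP replicates 1, 2, 3 or 4 the counts were 2 and 43, 7 and 45, 264 and 1149, and 44 and 88. Without IgG IP replicates 1, 2, 3 or 4 they were 103 and 275, 9 and 77, 10 and 95, and 9 and 62. Without IgG input replicates 1, 2, 3 or 4 they were 16 and 71, 10 and 59, 9 and 52, and 13 and 70. Without SFPQ input replicates 1 or 4 they were 11 and 83, and 17 and 75. Lmnb2 (0.64), Lpin1 (0.53), Bclaf1 (0.45), Sfpq (0.18), Bcl2l2 (0.16), Nasp (-0.30) and Srsf10 (-0.45) did not pass.

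The enrichment of SRSF10 beyond IgG was made in the same way. Bok, an mRNA of the Bcl2 protein family, stood at 1010 ± 329 CPM in the SRSF10 IP against 141 ± 33.0 CPM in the IgG IP (SD, n = 4). The inputs stood at 199 ± 20.9 and 174 ± 16.3 CPM (log2 difference 2.65, SE 0.35, adjusted p = 0.00196). Ahnak2 had a difference of 3.09 (SE 0.48, adjusted p = 0.00626), Mas1l, a receptor gene, of 2.57 (SE 0.38, adjusted p = 0.00477) and Faap20, a Fanconi anaemia protein, of 2.68 (SE 0.46, adjusted p = 0.00877). Prrg1, a membrane protein, was lower (-2.17, SE 0.36, adjusted p = 0.00633). These 5 passed the threshold in all 16 fits that left out 1 library. Filip1l (3.23), the chaperone Hsp90aa1 (2.39), Stard9 (2.39) and Osbpl7 (2.33) were higher. Lower were Xiap, an inhibitor of apoptosis (-1.84), Nufip2 (-1.82), Tbl1xr1 (-1.74), Ptp4a1 (-1.71) and Wasf3 (-1.67). These 9 missed the threshold in 3 to 14 of the 16 fits, with adjusted p of up to 0.132. Each also missed it with library size only, with no filter, in the 16 libraries alone or without the 4 libraries with over 4% mitochondrial rRNA. Of 33 genes of the axonal cytoskeleton 1 rose, the linker Dst (1.99, SE 0.38, adjusted p = 0.0187; 4 higher and 1 lower adjusted over the list alone). As a list these genes had a median of 0.47 (adjusted p = 0.0167, and adjusted p = 0.931 with an estimated correlation). That list's call was lost with limma voom (adjusted p = 0.0901), without the 4 libraries with over 4% mitochondrial rRNA (0.239). It was also lost without IgG input replicate 2 (0.0932), IgG IP replicate 3 (0.0902), SRSF10 input replicate 3 (0.0798) or SRSF10 input replicate 4 (0.0515). Dst missed the threshold with library size only, without those 4 libraries and without IgG IP replicate 4 (0.05). Filip1l and Stard9 overlap another gene with a symbol, and Dst, Hsp90aa1 and Wasf3 genes without one.

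In total, edgeR called 47 genes higher and 45 lower for SRSF10 beyond IgG, against 20 and 8 with scaling by library size only. DESeq2 called 145 and 193, limma voom 224 and 159, IP against IgG IP without inputs 304 and 427, and the 16 libraries alone 20 and 4. A fit with no filter gave 26 and 10, a filter at 10 CPM 73 and 98, and the fit without the 4 libraries with over 4% mitochondrial rRNA 33 and 25. Without SRSF10 IP replicates 1, 2 or 4 the counts were 47 and 88, 111 and 41, and 15 and 6. Without SRSF10 input replicates 1, 2 or 4 they were 25 and 15, 28 and 19, and 18 and 10. With IgG IP replicates 1, 2, 3 or 4 left out they were 13 and 6, 25 and 10, 41 and 81, and 14 and 10, and with IgG input replicates 1, 2, 3 or 4 left out 20 and 8, 25 and 10, 18 and 9, and 13 and 6. Nasp (1.03), Bclaf1 (0.46), Lpin1 (0.29), Lmnb2 (0.22), Sfpq (0.21), Bcl2l2 (-0.41) and Srsf10 (-0.74) did not pass.

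SFPQ and SRSF10 were also set against each other, in a contrast with no IgG group, with the spread estimated from all 24 libraries. Luc7l3, Pnisr and Srrm2 were lower with SFPQ than with SRSF10. Luc7l3 stood at 29.1 ± 11.4 CPM in the SFPQ IP and 288 ± 119 CPM in the SRSF10 IP (SD, n = 4; log2 difference -3.25, SE 0.41, adjusted p = 0.000116), and Pnisr at 29.5 ± 5.74 and 282 ± 66.3 CPM (-3.00, SE 0.40, adjusted p = 0.00018). Srrm2 stood at 157 ± 39.8 and 609 ± 257 CPM (-1.93, SE 0.37, adjusted p = 0.00402). Nrxn1 (1.48), Lsamp (1.66), the kinase Prkaa2 (2.47), Megf11 (2.88) and the zinc finger gene Zbtb41 (2.44) stood higher with SFPQ, at adjusted p from 0.00018 to 0.00342. The imprinted RNA RGD1566401 stood at 128 ± 73.4 CPM in the SFPQ IP and 1540 ± 863 CPM in the SRSF10 IP (-3.32, SE 0.72, adjusted p = 0.00861). Each of these genes passed the threshold in all 16 fits that left out 1 library.

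**Figure D3:**
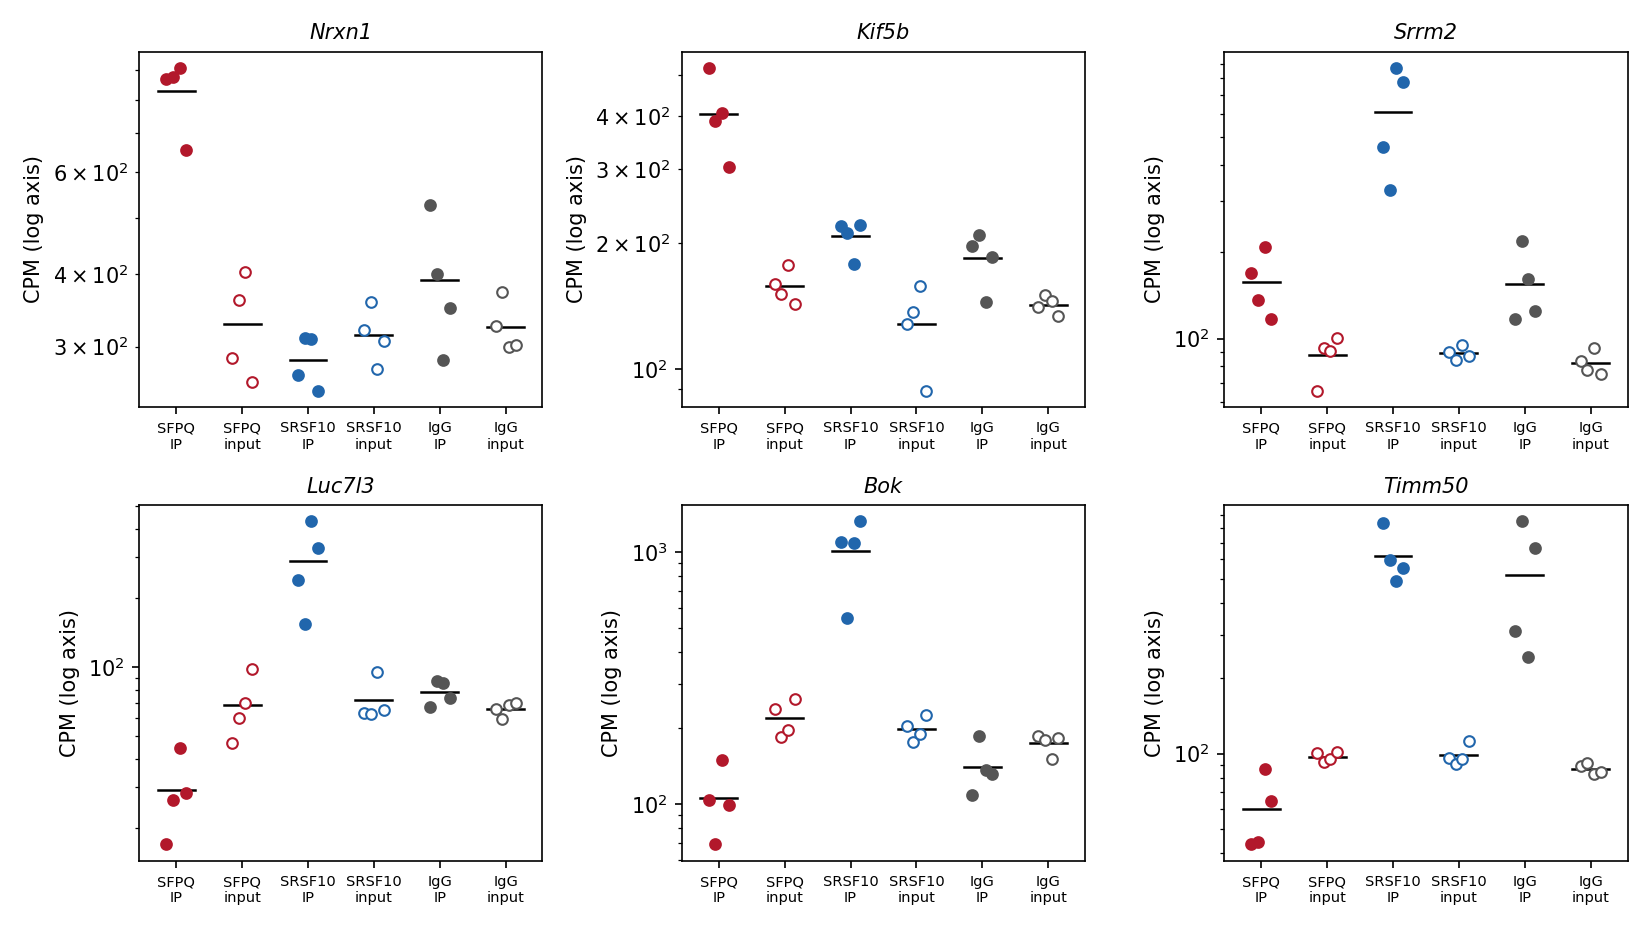
CPM (log axis) of Nrxn1, Kif5b, Srrm2, Luc7l3, Bok and Timm50 in each library of the 6 groups, where points are libraries (filled for IP, open for input) and lines are group means. Nrxn1 and Kif5b lie highest in the SFPQ IP (means of 826 and 405 CPM), Srrm2, Luc7l3 and Bok in the SRSF10 IP (609, 288 and 1010 CPM), and Timm50 in the SRSF10 and IgG IPs (620 and 518 CPM).

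Xiap (2.48), Uprt (2.43), Foxo3 (2.40) and Ttbk2 (2.27) were higher with SFPQ than with SRSF10 in all 16 fits, and mt-Rnr2 (-7.05), Cox8a (-5.11), Rpl35 (-4.96) and Wdr38 (-4.92) lower. Alg10 (2.50) lost the call in 2 fits (adjusted p of up to 0.0584 without SRSF10 input replicate 2), and Rn7sl1 and Uqcr10 (-4.64) in 1, without SRSF10 IP replicate 3 (0.0537 and 0.056). Alg10 and Uqcr10 also lost it in the 16 libraries alone, and Rn7sl1 with limma voom. Wdr38 and Rpl35 overlap each other, Ttbk2 overlaps Stard9, and Cox8a and Uqcr10 each overlap another gene with a symbol, so the source of their reads is uncertain. Megf11, Srrm2, Nrxn1, Lsamp and Tug1 overlap genes without a symbol. Of 75 ribosomal protein mRNAs 37 were lower with SFPQ (69 adjusted over the list alone), with a median of -2.70 (adjusted p = 1.65e-18, and adjusted p = 0.576 with an estimated correlation). Oxidative phosphorylation had 38 of 73 genes lower (58 adjusted over the list alone) and a median of -2.53 (adjusted p = 1.96e-16, and adjusted p = 0.576 with an estimated correlation). Without SRSF10 IP replicate 3, the library with the highest ribosomal protein share, these medians were -1.34 and -1.13, both still past the threshold. Among translation elongation and TOP mRNAs 4 of 25 were lower (10 lower and 2 higher adjusted over the list alone), with a median of -0.79 (adjusted p = 0.0228, and adjusted p = 0.606 with an estimated correlation). Histones had 3 of 21 genes lower and 1 higher (8 and 1 adjusted over the list alone), and a median of -1.84 (adjusted p = 0.0104, and adjusted p = 0.576 with an estimated correlation). Of the 7 long noncoding RNAs 3 were lower and 1, Tug1, higher (4 and 1 adjusted over the list alone), with a median of -1.49 (adjusted p = 0.0415, and adjusted p = 0.576 with an estimated correlation). SR splicing factors had 5 of 28 lower and 2 higher (7 and 2 adjusted over the list alone), and a median of -0.22 (adjusted p = 0.0491, and adjusted p = 0.576 with an estimated correlation).

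Voltage-gated channels stood higher with SFPQ, 7 of 40 (8 higher and 1 lower adjusted over the list alone), with a median of 0.55 (adjusted p = 8.65e-05, and adjusted p = 0.576 with an estimated correlation). Motor genes had 3 of 31 higher and 2 lower (5 and 2 adjusted over the list alone), and a median of 0.49 (adjusted p = 0.0164, and adjusted p = 0.576 with an estimated correlation). Long neuronal genes had 2 of 35 higher and 2 lower (2 and 2 adjusted over the list alone), and a median of 0.50 (adjusted p = 0.0164, and adjusted p = 0.576 with an estimated correlation). Of 23 hnRNP proteins 1, Hnrnpa3, was higher (0 adjusted over the list alone), with a median of 0.35 (adjusted p = 0.0194, and adjusted p = 0.576 with an estimated correlation). Hnrnpa3 lost the call in 9 of the 16 fits without 1 library (adjusted p of up to 0.0761 without SFPQ IP replicate 1), at 10 CPM, with no filter and in the 16 libraries alone. The call of SR splicing factors was lost with library size only (adjusted p = 0.103), limma voom (0.0543), no filter (0.0749) and in 10 of 16 fits without 1 library (up to 0.109 without SRSF10 IP replicate 4). That of long noncoding RNAs was lost at 10 CPM (0.0685), with limma voom (0.124) and in 6 fits (up to 0.158 without SFPQ IP replicate 3). TOP mRNAs lost theirs in 5 fits (up to 0.164 without SRSF10 IP replicate 3) and motors in 1 (0.0598 without SRSF10 input replicate 2). Histones lost theirs with limma voom (0.0543) and without SRSF10 IP replicate 3 (0.0867). SR splicing factors and histones also lost the call without the 4 libraries with over 4% mitochondrial rRNA (0.0785 and 0.0711).

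In total, 598 genes were higher and 1003 lower with SFPQ than with SRSF10 by edgeR. DESeq2 called 943 and 1792, limma voom 1502 and 2876, SFPQ IP against SRSF10 IP without inputs 2098 and 3290, the 16 libraries alone 174 and 196, and a filter at 10 CPM 930 higher. Without SFPQ IP replicates 1, 2, 3 or 4 the counts were 274 and 304, 251 and 277, 917 and 2185, and 511 and 638. Without SFPQ input replicates 1 or 4 they were 385 and 694, and 373 and 441, and without SRSF10 IP replicates 2 or 3, 927 and 1604, and 348 and 463. With SRSF10 input replicates 1, 2, 3 or 4 left out they were 348 and 400, 334 and 433, 884 and 1883, and 551 and 661. Nasp had a difference of -1.33 (adjusted p = 0.0692), Bcl2l2 of 0.58, Lmnb2 of 0.42, Srsf10 of 0.29, Lpin1 of 0.24, Sfpq of -0.02 (0.09 with library size only) and Bclaf1 of -0.01 (0.10 with library size only), none past the threshold.

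Few genes passed the threshold in both enrichments beyond IgG. Ankrd11, a chromatin regulator, was higher in both (1.34 with SFPQ and 1.48 with SRSF10). Csnk1e, Nmnat1, Ccni and Atxn7l1 were lower in both (-1.27 to -1.84 with SFPQ, -1.22 to -1.60 with SRSF10). These 5 were named after their values were seen. Independent lists of these sizes would share 0.121 higher and 0.403 lower genes, and unchanged groups simulated 20 times against the same IgG libraries shared 0. That 0 gives no chance value, since at most 2 genes were called in any simulated list. The fold changes of both enrichments correlated across genes at 0.079, against 0.463 to 0.504 in the simulation, with a covariance of 0.072 against 0.364. The simulation held no real changes and gave all groups the same spread per gene. The real biological coefficient of variation was lowest in the IgG IP and input (0.379 and 0.259, against 0.404 to 0.553 in the other groups). The simulated values here and below therefore give no chance value for the real ones. Genes are not independent replicates. With the IgG libraries split between both enrichments in 6 ways, 0 genes were shared by edgeR in either direction, and the correlation of the enrichments ran from -0.192 to 0.069. These splits left 0 genes higher and 2 to 20 lower with SFPQ, and 0 to 4 higher and 0 to 9 lower with SRSF10, too few to show sharing. In the same splits IP against IgG IP without inputs shared 3 to 12 higher and 5 to 24 lower, against 0 to 5 and 0 to 1 in the simulation, and 1 to 41 were called in opposite directions. With IgG replicates 3 and 4 set against SFPQ the 24 shared lower genes were under the 26.5 of independent lists, with 41 opposite. On all libraries IP against IgG IP without inputs shared 55 higher and 90 lower (17.6 and 40.7 for independent lists), with 55 opposite and a correlation of -0.212 (0.369 to 0.413 in the simulation). DESeq2 shared 16 and 27 (3.2 and 9.55), with 9 opposite.

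The 3 groups of inputs were compared with each other to see whether they differed. edgeR called 0 of 16294 genes, with 344 at unadjusted p under 0.05, and DESeq2 and limma voom also called 0. Mitochondrial rRNA ran from 1.88% to 5.87% in the SFPQ inputs, from 1.91% to 7.33% in the SRSF10 inputs and from 2.09% to 3.36% in the IgG inputs.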

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

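The tests that weigh an explanation here, the other splits of the libraries included, were chosen after the results had been seen, apart from the test for lysate carried over into SRSF10 IP replicate 3.

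Differences between antibodies passed a test of the difference itself for 188 genes with SFPQ beyond IgG, 92 with SRSF10 beyond IgG and 1601 between SFPQ and SRSF10. Among the gene lists, SFPQ beyond IgG differed for long neuronal genes (median log2 0.45), long noncoding RNAs (-1.36), hnRNP proteins (0.31), ribosomal proteins (-2.06), oxidative phosphorylation (-2.06), histones (-1.49), motors (0.67), channels (0.58) and secretory genes (0.52), and SRSF10 beyond IgG for the axonal cytoskeleton (0.47). SFPQ and SRSF10 differed from each other for long neuronal genes (0.50), long noncoding RNAs (-1.49), SR splicing factors (-0.22), hnRNP proteins (0.35), ribosomal proteins (-2.70), oxidative phosphorylation (-2.53), translation elongation and TOP mRNAs (-0.79), histones (-1.84), motors (0.49) and channels (0.55). With an estimated correlation none of these list calls held. With fry none of those beyond IgG held (adjusted p from 0.0818 to 0.138 with SFPQ, 0.566 with SRSF10). Between SFPQ and SRSF10, long noncoding RNAs, SR splicing factors and hnRNP proteins held with fry (adjusted p = 0.0406 each). The other lists did not (0.0668 to 0.229).

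For every one of the 6 tests of IPs except SRSF10 IP against input, no other split of their libraries called as many genes. A share of 1 in 35, the smallest these splits allow, is under 0.05 for a test alone. It was not adjusted over the 6 tests, so chance was not excluded for them together. The real split was the only 1 of 35 with as many genes for the SFPQ IP (6001 genes, highest other 0), SFPQ beyond IgG (188, highest other 122), SRSF10 beyond IgG (92, highest other 0) and SFPQ against SRSF10 (1601, highest other 0). The splits of SFPQ against SRSF10 exchange IP libraries only, and those of the same number correlated at 0.26, 0.37, 0.64 and 0.11. Read as pairs, they leave as few splits that part every pair as the IgG IP below, so chance stays open there. For the IgG IP, taken as paired with its input by number, the real split was also the only 1 of 35 with 32 genes (highest other 0). The 8 splits that part every pair are too few for a share under 0.05; the other 7 exchange IP and input in some pairs and gave 0 genes. For the SRSF10 IP, 4 of 35 splits gave at least the real 1365 genes, the highest other 3951, so chance was not excluded. The 3 other splits, with 3951, 1889 and 1843 genes, all kept IP replicate 3 together with input replicates 3 and 4, which points to a structure of the samples. For the inputs the splits decide nothing, since with a real count of 0 all 100 splits give at least as many (highest other 2).

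The first pattern is the lower share of ribosomal protein mRNA and mitochondrial rRNA in the SFPQ IP. For ribosomal protein mRNA the values argue against libraries with over 4% mitochondrial rRNA as the cause. Its median was -2.63 without those 4. Only SFPQ input replicate 4 of them belongs to this comparison, and the others are SRSF10 libraries, so the fit tests little more than that input. Both mitochondrial rRNAs stayed past the threshold in it. The values also argue against the scaling, since the ribosomal protein median was -2.82 with library size only. A loss that the control IP shares in full is argued against for mt-Rnr2, which had a log2 of -5.81 beyond IgG. For the ribosomal protein list the mean log2 CPM had a difference of -1.89 beyond IgG (SE 0.62 between libraries). This lay past the bound set for the test, but its SE takes IP and input libraries as independent. Beyond IgG the list did not pass with fry (adjusted p = 0.138) or with an estimated correlation (adjusted p = 0.485), and edgeR called 0 of its 75 genes. A loss shared in part or in full stays open for ribosomal protein mRNA. Its median was -0.92 in the IgG IP, and its shares in the SFPQ and IgG IPs gave an exact permutation p = 0.0857. Binding by SFPQ itself and a bias by transcript length stay open, the latter untested since transcript lengths were not used here.

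The second pattern is the set of 32 genes enriched by the control antibody. Of these, 23 were also higher in the SRSF10 IP, where 1.9 would fall by chance, with a median log2 of 1.36, so a background shared with the SRSF10 antibody is consistent with the values. In the SFPQ IP 14 of the 32 were higher, where 5.6 would fall by chance, and 1 lower, with a median of 0.53. With SFPQ beyond IgG 11 were lower (1 with SRSF10), a count that is raised by choosing genes that were high in the same IgG libraries. A background shared by all 3 antibodies stays undecided, since 14 lies between the bounds set for the test (at least 16 of the 32 for it, under 8 against it), and binding of these RNAs by SRSF10 itself stays open and untested.

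The third pattern is SRSF10 IP replicate 3, which lay close to its input. Over 1213 genes called higher without that pair, its median log2 ratio of IP to input was 0.51, against a mean of 1.47 (SD 0.33) in the other 3, and lysate carried over into that IP could give this value. Leaving out each replicate in the same way gave ratios of 0.88, 0.67, 0.35 and 1.3 to the mean of the others, so replicate 3 was the lowest. Lower depth was not decided. With the SRSF10 libraries thinned to 10.59 M counts the other 3 kept a mean of 1.45 (SD 0.32) against 0.50 in replicate 3. Thinning leaves the expected share of each gene unchanged. It shows only that fewer counts drawn from the same libraries do not lower the ratio, and could not test anything else that may come with a shallow library. No biological explanation was tested.

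Single libraries far from the other 3 of their group are listed next with the gap as a share of the group's range; 37 of 349 groups of values passed the limit, and chance flags about 1 in 20 groups, here about 17. For whole libraries these were the total counts of SFPQ IP replicate 3 (0.845; 20.35 M, nearest 21.22), and in SFPQ input replicate 4 the genes with a count (0.985; 15940, nearest 18430), the share of the top 10 genes (0.885; 13.57%, nearest 8.106%) and mitochondrial rRNA (0.891; 5.873%, nearest 2.316%). The ribosomal protein share of SRSF10 IP replicate 3 was a further one (0.838; 4.685%, nearest 1.322%).

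For gene lists, by mean log2 CPM, SRSF10 IP replicate 3 stood apart in paraspeckle proteins (0.905; 5.314, nearest 5.636) and oxidative phosphorylation (0.856; 9.558, nearest 7.349), and SFPQ input replicate 4 in mitochondrially encoded genes (0.862; 13.73, nearest 12.1) and the Bcl2 family and lamins (0.878; 4.641, nearest 4.762). IgG input replicate 2 stood apart in histones (0.927; 1.781, nearest 2.389), synapse genes (0.935; 6.882, nearest 6.456) and glia (0.841; 2.258, nearest 3.863). Glia were also low in SRSF10 input replicate 2 (0.839; 1.868, nearest 3.832) and IgG IP replicate 2 (0.893; 1.748, nearest 3.821), and proliferation in SRSF10 IP replicate 2 (0.938; 1.912, nearest 3.759). In the IgG IP the axonal cytoskeleton was low in replicate 3 (0.99; 9.075, nearest 9.306), channels high in replicate 1 (0.891; 5.184, nearest 4.799) and secretory genes low in replicate 2 (0.83; 6.086, nearest 6.865).

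For genes, by CPM, SFPQ input replicate 4 stood apart in Atp5e (0.838; 615.6, nearest 233.5), Uqcr10 (0.916; 760.4, nearest 308.4), mt-Rnr1 (0.916; 2843, nearest 879.7) and mt-Rnr2 (0.918; 65060, nearest 21930). SFPQ IP replicate 3 did in Uqcr10 (0.852; 21.09, nearest 8.664), mt-Rnr1 (0.842; 45.92, nearest 24.61) and Dpy19l4 (0.872; 21.49, nearest 37.48). SRSF10 IP replicate 3 did in Hist1h1d (0.86; 204.4, nearest 44.71), Wdr38 (0.871; 74.15, nearest 14.71), mt-Rnr2 (0.843; 126500, nearest 26460), Rn7sl1 (0.891; 84.4, nearest 10.45), Uqcr10 (0.951; 1618, nearest 153.2), Rpl35 (0.869; 3460, nearest 625.4) and Cox8a (0.881; 6508, nearest 1083). The others were Ahnak2 in SRSF10 IP replicate 4 (0.848; 756, nearest 283.9), Cdkn1b in SRSF10 input replicate 4 (0.863; 34.08, nearest 20.37), Sfpq in SFPQ input replicate 2 (0.859; 77.65, nearest 55.35), Lpin1 in SFPQ IP replicate 2 (0.84; 91.94, nearest 59.68) and Nasp in IgG input replicate 2 (0.924; 22.71, nearest 28.8).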

How the results depend on the processing

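The fit without the 4 libraries with over 4% mitochondrial rRNA was chosen after seeing the data. For named genes, 2125 values kept their direction and side of the threshold under the alternatives that keep all libraries of a group or leave out those 4, 86 no longer passed, 266 newly passed and 0 called genes reversed; with 1 library left out these were 2517, 281 and 50. For lists they were 1308, 95 and 40, and 1419, 45 and 38 with 10 reversed. A sign changed in 182 uncalled values. The cause was not tested for any of the changes below, apart from fewer libraries in the fits that leave some out. Libraries of SRSF10 had the fewest counts, from 10.6 M. Whether depth limited its calls was not shown: of simulated 4-fold changes 65.2% were recovered in the SRSF10 IP and 53% in the deeper SFPQ IP, and of 2-fold changes 11.9% and 6%.

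SFPQ IP genes higher numbered 2869: 4473 with limma voom and 1884 at a log2 of at least 1; leaving out 1 library gave 2004 to 3072 higher and 2295 to 3570 lower. SRSF10 IP genes higher numbered 977: 1543 with limma voom and 31 with its own groups only (433 to 1672 with 1 library left out). The genes lower numbered 388: 589 with DESeq2, 211 with library size only, 779 with limma voom, 94 at a log2 of at least 1, 193 with no filter and 0 with its own groups only (104 to 1363). IgG IP genes higher numbered 32: 62 at 10 CPM, 147 with DESeq2, 15 with library size only, 504 with limma voom, 17 with no filter, 9 with its own groups only and 99 without the 4 libraries (6 to 84). The genes lower numbered 0: 2, 8 and 211 at 10 CPM, with DESeq2 and with limma voom, and 2 without the 4 libraries (0 to 2). Inputs gave 0 under every alternative.

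SFPQ beyond IgG genes higher numbered 42: 183 at 10 CPM, 360 with DESeq2, 941 without inputs, 24 with library size only, 1983 with limma voom, 14 with no filter, 523 with its own groups only and 279 without the 4 libraries (2 to 264). The genes lower numbered 146: 261 at 10 CPM, 806 with DESeq2, 1554 without inputs, 2910 with limma voom, 1172 with its own groups only and 824 without the 4 libraries (43 to 1149). SRSF10 beyond IgG genes higher numbered 47: 73 at 10 CPM, 145 with DESeq2, 304 without inputs, 20 with library size only, 224 with limma voom, 26 with no filter and 20 with its own groups only (13 to 111). The genes lower numbered 45: 98, 193, 427, 8, 159, 10 and 4 in the same order, and 25 without the 4 libraries (6 to 88). SFPQ against SRSF10 genes higher numbered 598: 930 at 10 CPM, 943 with DESeq2, 2098 without inputs, 1502 with limma voom and 174 with its own groups only (251 to 927). The genes lower numbered 1003: 1792 with DESeq2, 3290 without inputs, 2876 with limma voom and 196 with its own groups only (277 to 2185). Genes shared by both enrichments numbered 1 higher and 4 lower: 16 and 27 with DESeq2, 55 and 90 without inputs, 2 and 2 without the 4 libraries.

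Of the 12 pairs of IP and input with the same number, 10 correlated over 0.1 (SFPQ pair 3 at -0.21 and SRSF10 pair 4 at -0.015 did not) and 9 correlated best with their own number. The labels do not say that a number marks a shared lysate. All 4 IgG pairs were over 0.1, so by the rule set beforehand the numbers were taken to pair the IgG IP with its input. There a replicate block of antibody and number gave 44 higher, ended the call of Scn2a, called RGD1566401 and Snhg11 and changed no other call. In the other comparisons not every pair was over 0.1, the rule set beforehand, so those libraries were taken to share only a number. SFPQ and SRSF10 IPs of the same number correlated at 0.26, 0.37, 0.64 and 0.11, but their comparison also holds the pairs of IP and input named above. SRSF10 and IgG IPs of the same number correlated at 0.57, 0.5, 0.54 and -0.19, and SFPQ and IgG IPs at 0.57, -0.16, 0.2 and 0.3. Pairing in part of these libraries stays open, and fits without the block may misstate their spread. In these other comparisons the same block of antibody and number gave 792 lower with SRSF10, 649 and 1521 for SFPQ beyond IgG, 92 and 115 for SRSF10 beyond IgG, and 1282 and 2109 for SFPQ against SRSF10. Under it hnRNP proteins with SFPQ beyond IgG (0.32, adjusted p = 0.0541) and SR splicing factors in SFPQ against SRSF10 (-0.16, adjusted p = 0.0557) were not called. A replicate block of the number across antibodies gave 50 and 2 with IgG, 315 and 1138 for SFPQ beyond IgG, 84 lower for SRSF10 beyond IgG, and 955 and 1932 for SFPQ against SRSF10.

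Medians of lists that reversed were, with 1 library left out, -1.62 to 0.43 for ribosomal proteins in the SRSF10 IP (0.43, 0.03 and 0.08 when reversed), -1.56 to 0.45 for oxidative phosphorylation (0.45, 0.06, 0.04 and 0.05), -0.19 to 0.28 for fibroblast genes in the IgG IP (-0.14), and -0.70 to 1.37 and -0.85 to 1.2 for ribosomal proteins and oxidative phosphorylation with SRSF10 beyond IgG (-0.70 and -0.85, past the threshold without SRSF10 IP replicate 3).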

Other observations

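In the SFPQ IP, several gene lists held both genes that rose and genes that fell. Over all genes tested 17.6% rose and 19.2% fell, so both directions within a list do not set it apart. Of 35 synapse and vesicle release genes, 14 rose and 7 fell over input (18 and 7 adjusted over the list alone, median log2 0.74, adjusted p = 0.111): Nrxn1 rose by 1.33, while Vamp2, the vesicle SNARE, and Cplx1, a complexin, fell by 1.41 and 1.30. Of 33 genes of the axonal cytoskeleton, 12 rose and 7 fell (13 and 7 adjusted over the list alone, median 0.16, adjusted p = 0.453), with the microtubule proteins Map1b (1.74) and Map1a (1.28) higher and Cfl1, an actin-severing cofilin, lower (-2.08). Of 30 sensory identity genes, 8 rose and 4 fell (8 and 4 adjusted over the list alone, median 0.42, adjusted p = 0.453), with the mechanosensitive channel Piezo2 (1.30) and the transcription factor Etv1 (1.09) higher and the ubiquitin hydrolase Uchl1 lower (-1.62). In the Bcl2 family and lamins, 5 of 22 fell and 2 rose (5 and 2 adjusted over the list alone; median 0.02, adjusted p = 0.495; -0.02 with DESeq2), the lower ones including the mitophagy receptor Bnip3 (-2.01), the pore-forming Bak1 (-1.58) and the nuclear envelope protein Emd (-1.30). Of 26 immediate early and stress genes, 8 fell and 4 rose (8 and 4 adjusted over the list alone, median -0.30, adjusted p = 0.453), with the chaperone Hsp90ab1 at 1.01, the cochaperone Dnajb1 at -0.97 and the small heat shock protein Hspb1 at -2.71.

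Of 25 paraspeckle and DBHS-partner proteins, 7 rose and 3 fell in the SFPQ IP (7 and 3 adjusted over the list alone, median 0.17, adjusted p = 0.453), with Hnrnpm (1.34) and Matr3 (0.85) higher and the cold-inducible Rbm3 lower (-1.42). Hnrnpm overlaps another gene, so its value is uncertain. Of 28 SR splicing factors 5 rose and 3 fell (4 and 3 adjusted over the list alone, median 0.11, adjusted p = 0.495), of 23 hnRNP proteins 8 and 2 (9 and 2 adjusted over the list alone, median 0.31, adjusted p = 0.0928) and of 7 long noncoding RNAs 1 and 1 (1 and 1 adjusted over the list alone, median -0.42, adjusted p = 0.586). Among other cell types, 3 of 23 glial genes fell (3 adjusted over the list alone; median -0.48, adjusted p = 0.461), led by the lipid carrier Fabp5 (-2.41), while 4 of 23 fibroblast genes rose and 2 fell (3 and 2 adjusted over the list alone, median 0.51, adjusted p = 0.615). Of 19 genes of endothelium and blood 3 fell (2 adjusted over the list alone; median -1.10, adjusted p = 0.453), and of 29 proliferation genes 1 fell (0 adjusted over the list alone; median 0.26, adjusted p = 0.461). In the 12 inputs the sensory identity list held 0.915 ± 0.139% of counts (SD), with Uchl1 at 2870 and the neurotrophin receptor Ngfr at 2120 CPM. The glial list held 0.181 ± 0.0405%, fibroblasts 0.172 ± 0.0606%, proliferation 0.0268 ± 0.0102% and endothelium and blood 0.00347 ± 0.00155%. Most of the glial share came from Fabp5 (1200 ± 662 CPM) and L1cam (186 ± 52 CPM), so it does not measure glial content. None of these shares gives a proportion of cells. The signs of a list's median, mean and test differed in 14 of 126 pairs of list and comparison, 0 of them called.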
